A study of Mus musculus with 4 samples.

How the data were processed

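The series holds 4 RNA libraries from mouse bone-marrow-derived macrophages. Bone marrow cells of C57BL/6 mice were grown with macrophage colony-stimulating factor (M-CSF, the growth factor that drives macrophage differentiation) for 7 days and then cultured with MC38 cells, a mouse colon carcinoma line, for 24 hours. The mice carried loxP-flanked Mettl3 alleles alone (WT) or together with a Cre recombinase driven by the lysozyme M promoter, which is active in myeloid cells (Mettl3 cKO). Mettl3 is the catalytic subunit of the enzyme that writes N6-methyladenosine (m6A) into messenger RNA. Each genotype has 1 library of fragments pulled down with an m6A antibody (IP) and 1 library of fragments before the pulldown (input). Per the labels' protocols, poly(A) RNA was purified from 50 µg of total RNA with an integrity number above 7.0, fragmented at 86 °C for 7 minutes, and incubated with the antibody for 2 hours. Libraries had 8 PCR cycles, inserts of 300 bp on average and paired reads of 150 bp, and the second strand was marked with dUTP, so that the libraries keep strand.

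The labels give 1 sample per group, so no comparison has replicates. No p-value of its own was computed, and each difference compares these libraries and has no replicate check. The groups come from the titles and genotypes in the labels. Per the submitters' processing notes, the build was mm10 and the tools were fastp, HISAT2, HOMER, ChIPseeker, StringTie and edgeR, listed without role or order. The peak caller, the tool versions and the way IP and input libraries were scaled to each other are not given in the sources used here.

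There were 4 deposited tables. A peak list per genotype gives, per the file headers, the log2 fold of IP over input at each peak called from 1 IP and 1 input library, with the authors' p-value and adjusted p-value. Every listed p lay below 0.05 and every log2 fold above 0. The authors' deposited table of differential peaks gives the log2 IP over input in the cKO, in the WT and their difference, cKO minus WT, with a p-value and an adjusted p-value, and holds only peaks with p below 0.05. Its WT column followed the WT peak list at 1619 identical positions (median difference -0.04, Pearson's r across peaks 1.00) and its cKO column the cKO peak list at 1444 positions (-0.05, r 1.00), which settles which column belongs to which genotype. A gene table repeats these peaks and adds, per the file headers, the FPKM (fragments scaled to transcript length and library size) of each peak's gene in the 2 input libraries as the authors deposited them. Input FPKM values were therefore held only for the 7307 genes with a value and a listed differential peak, and the other genes were not analysed here. This leaves Mettl3 without an input value.

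Total read counts per library were not analysed here, so the depth behind each value is unknown. Of 108 genes with both FPKM values above 0 and below 0.1, at most 2 shared a ratio of the 2 values to 4 digits, so the values show no steps of whole reads and the relative depth could not be read from them. Intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting error only. Start positions in the tables count from 0: a start lay 1 below the annotated gene start in 4799 WT peaks and equalled it in 0. Positions are given 1-based on mm10. Gene identifiers matched GENCODE release M21 in 99.8% of the peaks of each list, with the same gene start in 99.5% of the WT peaks. A position spans introns between the outer ends of a peak, and 17.1% of WT and 16.2% of cKO peaks spanned over 5000 bp. Region names are the authors' annotation.

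Peak sets were compared with bedtools 2.31.1, on the same strand and with an overlap of at least 1 bp. Log2 IP over input was compared at peaks that overlapped one to one. Differential peaks were taken as the authors call them. Input differences are log2(FPKM + 1) in the cKO minus the WT for genes with a mean input FPKM of at least 1, a scale that understates changes of low genes. For each gene list, the median difference was given with a 95% interval from 2000 bootstrap draws of its members and with its percentile among 10000 random lists of the same size matched on mean FPKM in 10 bins. A list is called lower or higher at a percentile of at most 2.5 or of at least 97.5, which describes these libraries only. The 23 lists were fixed before the data were examined, as were most of the alternatives and the rule for named genes. That rule takes up to 4 members per list by absolute input difference, the 10 highest and 10 lowest genes in the input at mean FPKM of at least 5, the 10 largest rises and falls of a differential peak in such genes, the 5 peaks of highest enrichment per genotype in such genes, and Jak1, other JAK-STAT genes, Spred2, Socs1, Socs2, Socs3, Cish and the m6A machinery. Symbols that begin with Gm and a digit or end in Rik, and mitochondrial genes, were left out. The values of 1 list gene are not reported or drawn here, while list counts and medians include it.

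The comparison of genes with and without a WT peak had to depart from its design. Only 63 of 6079 genes lacked a WT peak, too few to draw lists from, so random lists were drawn from the genes with a peak and matched to those 63. The motif was GGAC followed by A, C or T, the core of the sequence context in which m6A is written, counted in exonic peak sequence on the M21 transcript that the authors assign. Control windows had the length of the peak, lay directly beside it on the same transcript and overlapped no peak, which left 16606 of 34645 placed WT peaks and 18126 of 36498 placed cKO peaks. For stop codons a comparison with uniform placement along the transcript was added after the windows had been seen. Motif-dense and motif-poor differential peaks, above or at most at the median motif density, were compared within quintiles of mean enrichment and quintiles of exonic length.

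For the peaks of each list, the number of lower peaks was set against 10000 random draws of differential peaks from the same quintiles of mean enrichment, a comparison added after the counts had been seen. The list percentile was tested on simulated differences at the mean levels of the 6079 real genes: of 100 lists of 12 genes, 2 passed the 97.5th percentile with no planted shift, 92 with a shift of 0.3 and 100 with a shift of 0.6 on the log2 scale. The simulated differences were independent normal draws and the lists were random genes. The test therefore does not give the rate for lists whose members vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were other pseudocounts and filters, centring on the median, stricter peak thresholds, a reciprocal overlap and another motif control. A change of the differential threshold by adjusted p or by size alone, the list medians without shared members, and the counts of gene group peaks by adjusted p were added after seeing the data.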

Results

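m6A sequencing was carried out on macrophages that had been cultured with MC38 colon carcinoma cells, to ask how loss of Mettl3 in myeloid cells changes m6A and the transcriptome of macrophages exposed to tumour cells. The data are 1 m6A IP and 1 input library of WT macrophages and 1 m6A IP and 1 input library of Mettl3 cKO macrophages. There are no replicates, so each difference below is between single libraries, and no spread between cultures is known. Total read counts were not analysed here, so the depth is unknown.

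The targeted gene was examined first. Mettl3 (chromosome 14, 52294841 to 52305128, minus strand, mm10) has no differential peak in the authors' deposited table, and its input level was not analysed here. The WT peak list held 2 peaks in Mettl3, at log2 IP over input of 1.37 in the 3' UTR and 1.33 in the 5' UTR. The cKO list held 4, in the 3' UTR at 1.45 and 0.86, in exonic sequence at 1.80 and in an intron at 1.30. Peaks in the gene do not check the deletion of its floxed part, so the genotype labels were not checked by these values.

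The first comparison asks where m6A peaks lay in each genotype and how many both shared. Peaks were found in both genotypes in similar numbers, with 36507 in the WT library pair over 13832 genes and 38697 in the cKO pair over 13993 genes. Of the genes, 13022 had a peak in both lists. Most peaks lay in 3' UTRs, at 56.2% of WT peaks (95% interval 55.7 to 56.7) and 55.7% of cKO peaks (55.2 to 56.2). Other exonic sequence held 22.9% and 22.7%, 5' UTRs 9.04% and 9.09%, exons of noncoding RNAs 7.04% and 7.13%, and introns 4.58% and 5.15%, in the WT and the cKO respectively. The median log2 IP over input, the authors' value per peak, was 1.22 in the WT list and 1.30 in the cKO list. The scaling of IP to input is not known, so a loss of m6A shared by all sites may not show in these numbers and medians. For the same reason, a higher value at a peak in the cKO need not mean more m6A there.

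Of the WT peaks, 73.2% (72.7 to 73.6) overlapped a cKO peak, and of the cKO peaks 71.3% (70.8 to 71.7) overlapped a WT peak. The share fell to 48.8% and 46.1% when the overlap had to cover at least 50% of both peaks. WT peaks without a cKO partner were weaker, with a median log2 of 0.95 against 1.31 in those with a partner. At the 19387 peaks that matched one to one, the cKO value exceeded the WT value by a median of 0.04 (95% bootstrap interval 0.04 to 0.05). The direction depended on the strength of the peak. In the strongest quintile, with a median log2 of 2.84, 68.8% of peaks were lower in the cKO, with a median difference of -0.22. In the middle quintile, with a median of 1.39, 33.5% were lower and the median difference was 0.15.

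Peaks and the windows beside them held at least 1 m6A motif about equally often, while motifs were denser in peaks, at 3.73 against 3.48 per kb in the WT and 3.53 against 3.47 in the cKO. It was present in 52.9% of WT peaks (52.1 to 53.6) and 52.9% of the windows beside them, and in 51.4% of cKO peaks (50.7 to 52.1) and 52.0% of the windows beside them. The same peak sequences held it in 45.9% and 45.4% after shuffling. Among peaks with at least 4-fold enrichment the share was 66.1% in WT peaks (64.2 to 67.9) against 63.1% beside them, and 61.0% in cKO peaks (59.1 to 62.9) against 59.2%, with 4.42 against 3.60 and 4.12 against 3.46 motifs per kb. A stop codon lay in 10.3% of WT peaks that had a free window and in 12.1% of those windows, and in 9.34% of such cKO peaks against 11.99%. Over all placed peaks of transcripts with a stop codon, 19.8% of WT peaks (19.3 to 20.2) and 18.4% of cKO peaks (17.96 to 18.79) held one, against 18.05% and 17.27% for uniform placement along the transcript.

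Ranked within each genotype's peak list, the strongest peaks in genes with a mean input FPKM of at least 5 differed between the lists. The authors' deposited table of differential peaks holds other values as high, such as 8.08 in the WT for Tmem168 and 7.05 in the cKO for Dnpep. In the WT list they lay in the 5' UTR of Fbln2 (log2 8.81), an intron of Fnip2 (7.31), the noncoding Mir703 (7.21), and the 5' UTRs of Btbd2 (6.85) and Pcbp2 (5.57). In the cKO list they lay in the 5' UTR of Alas1 (8.01), which encodes the first enzyme of haem synthesis, the 3' UTR of Ctso (6.96), exons of Mfap1a (5.87), and the 5' UTRs of Abr (5.23) and Spen (5.19). The read counts behind these peaks are unknown, so the difference between the lists was not read as one between the genotypes.

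The next comparison is between m6A enrichment in the cKO and in the WT. The authors' deposited table lists 10355 peaks in 7400 genes as different, 5063 higher and 5292 lower in the cKO. The split changes side with the size threshold. Among peaks with an adjusted p below 0.05 and an absolute log2 difference of at least 1, the authors' deposited table has 950 higher and 718 lower, so that the higher share goes from 48.9% to 57.0%. By region, 62.9% of differential 5' UTR peaks (59.6 to 66.2) and 58.3% of exonic peaks (56.0 to 60.6) were lower in the cKO, against 48.5% of 3' UTR peaks (47.3 to 49.7) and 36.9% of intronic peaks (32.2 to 41.8). At an adjusted p below 0.05 in the authors' deposited table these shares were 71.2%, 62.9%, 51.6% and 44.5%, so that the 3' UTR share changes side.

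Strong peaks were mostly lower and middling peaks mostly higher in the cKO. Of the quintile of differential peaks with the highest mean log2 IP over input, 85.5% (83.9 to 87.0) were lower. Of the middle quintile, 28.7% (26.8 to 30.7) were lower. At matched enrichment and exonic length, motif-dense peaks were lower more often than motif-poor peaks, by 6.71 percentage points (95% bootstrap interval 5.11 to 8.44, 9899 peaks).

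**Figure D1:**
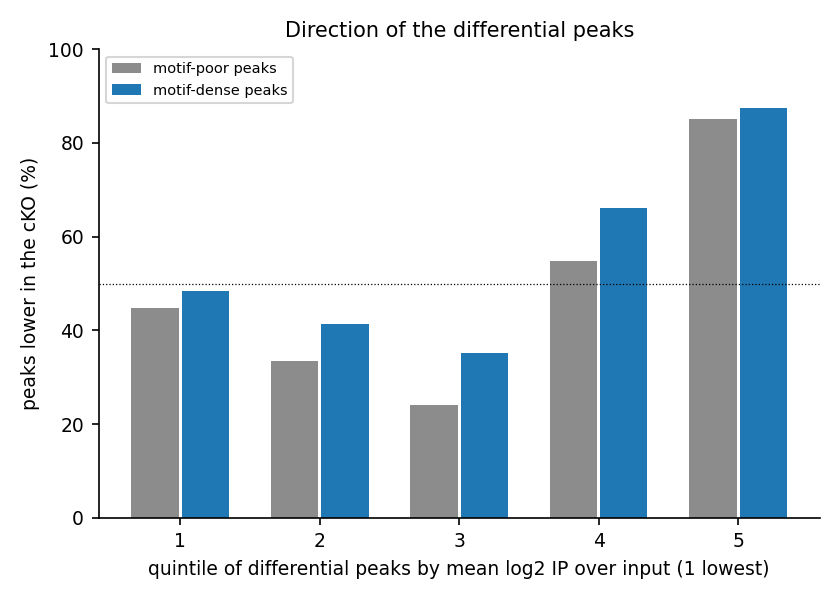
Share of the authors' differential peaks that were lower in the cKO (vertical axis, percent) by quintile of mean log2 IP over input (horizontal axis), for motif-poor peaks (grey) and motif-dense peaks (blue). The share was 24.0% in motif-poor and 35.1% in motif-dense peaks of the middle quintile, and 85.1% and 87.5% in the highest quintile.

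JAK-STAT genes, which relay cytokine signals from receptors to the nucleus, had more lower than higher peaks in the cKO, a number within the range that peak strength alone gave. Of 26 differential peaks in 19 of the 24 genes, 9 were higher and 17 lower in the authors' deposited table, and at an adjusted p below 0.05 it has 4 higher and 13 lower. Random differential peaks of the same enrichment quintiles gave 14.9 lower of 26 (95% of draws 10 to 19) and 11.5 of 17 (8 to 15). In Jak1, the kinase used by interferon and interleukin-6 family receptors (chromosome 4, 101152367 to 101265282, minus strand), the 3' UTR peak at 101152367 to 101154399 had a log2 IP over input of 2.81 in the WT and 2.33 in the cKO, a difference of -0.48 (adjusted p 6.74e-16 in the authors' deposited table). A second Jak1 peak, in exonic sequence at 101185280 to 101191504, differed by -0.39 (adjusted p 0.0863 in the authors' deposited table). The 3' UTR peaks of the feedback inhibitors Socs3 (-0.28), Cish (-0.32) and Socs2 (-0.50) and of Jak2 (-0.33) were lower as well, while another Socs2 peak in the 3' UTR was higher (5.07, adjusted p 0.105 in the authors' deposited table). Stat3 had 1 differential peak, in its 3' UTR, that was higher (0.24, adjusted p 0.0831 in the authors' deposited table), and Socs1 had 0. In Spred2, an inhibitor of the Ras-ERK pathway, the 3' UTR peak at chromosome 11, 20018082 to 20021982 went from 2.21 to 1.56 (adjusted p 8.75e-08 in the authors' deposited table).

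**Figure D2:**
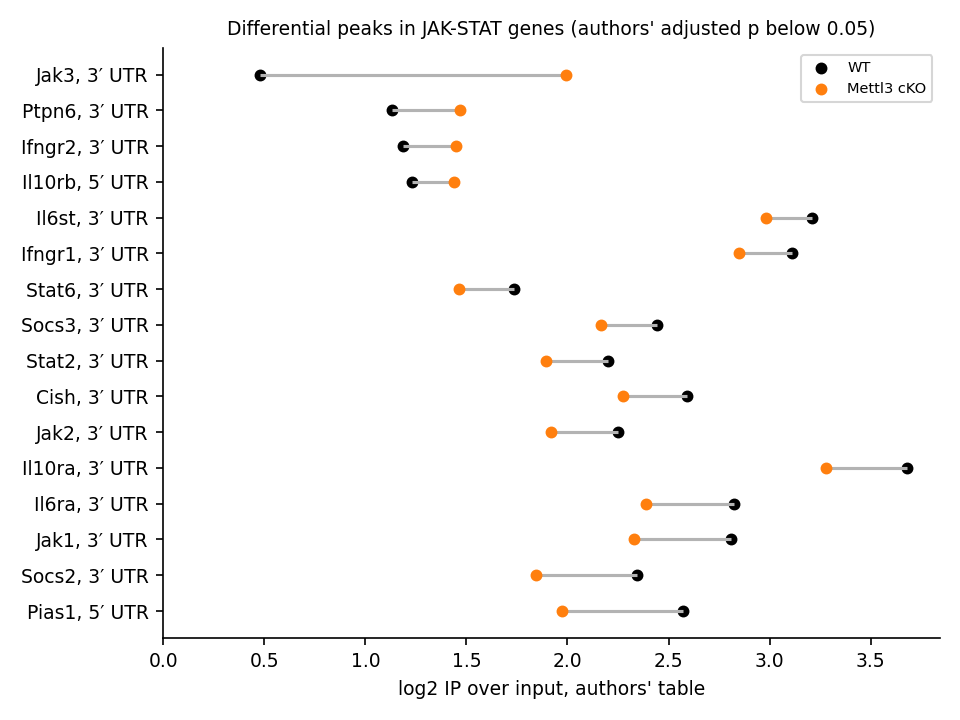
Log2 IP over input (horizontal axis) of 16 differential peaks in JAK-STAT genes with an adjusted p below 0.05 in the authors' deposited table, in the WT (black) and the cKO (orange), with 1 IP and 1 input library per genotype. Of the peaks drawn 12 were lower in the cKO, and the peaks of Il10rb, Ifngr2, Ptpn6 and Jak3 were higher.

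Transcripts known from other cells to carry m6A, such as Socs3, Klf4 and Tnfaip3, had 1 higher and 11 lower peaks in the authors' deposited table. Those of Klf4 and Tnfaip3, in their 3' UTRs, differed by -0.40 and -0.37. Genes of m6A writers and their partners had 2 higher and 6 lower peaks there, with the 3' UTR peak of Wtap, the subunit that holds the complex in nuclear speckles, at -0.73 and that of Zc3h13 at -0.36. The 2 higher peaks, in the 3' UTRs of Mettl14, the direct partner of Mettl3 (1.22), and Mettl16 (1.07), had larger differences at adjusted p of 0.0795 and 0.0630 in the authors' deposited table. Eraser and reader genes had 4 higher and 5 lower peaks there, with a 5' UTR peak of the demethylase gene Alkbh5 at -0.58 and a 3' UTR peak of the reader gene Ythdf2 at -0.31, and 3' UTR peaks of Hnrnpc at 0.85 and of Ythdf1 at 0.78 and -0.44. Cytokine and chemokine genes had 10 higher and 2 lower peaks in the authors' deposited table, among them the 3' UTR peaks of Cxcl1 (0.54), Cxcl3 (0.39) and Cxcl2 (0.38). These were weak peaks in the WT, at log2 0.98, 0.78 and 1.17. The input of the same genes, which is the denominator of these values, was lower in the cKO by -1.16, -1.07 and -0.82 in log2(FPKM + 1). Whether the lower input raised these values was not tested for these genes, and the rises were not read as gains of m6A. Macrophage identity genes had 13 higher and 10 lower, lysosome genes 17 and 9, antigen presentation genes 13 and 8, and MAPK-ERK genes 6 and 11. With the authors' call, in none of these groups did the number of lower peaks leave the range of 95% of random draws of differential peaks from the same enrichment quintiles, which was 5 to 11 of 12 for the known m6A transcripts and 2 to 8 of 12 for the cytokine genes. Mesenchymal genes had 9 higher and 3 lower peaks, within the range of 3 to 9 lower, and 7 higher and 0 lower at an adjusted p below 0.05 in the authors' deposited table, outside the range of 1 to 5.

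The largest single differences were ranked in genes with a mean input FPKM of at least 5, and most came with IP below input in 1 of the genotypes. The largest falls were in exons of Phgdh (-7.54), the first enzyme of serine synthesis, an intron of Sh2b2 (-6.80), exons of Ube2v1 (-6.08) and the 5' UTR of Ei24 (-5.89) in the authors' deposited table, followed by Mir703, Ywhaz, Tmem168, Vdac3, Btbd2 and Metap2 down to -4.52. The largest rises there were in exons of Loxl2 (11.20), a lysyl oxidase that crosslinks collagen, an intron of Mbtps1 (6.25), the 5' UTR of Dnpep (6.06) and the 3' UTR of Ube2k (5.87), followed by Ndrg1, Rragc, Tmx3, Uchl5, Gclm and Tstd2 down to 5.14. The adjusted p values of these 20 peaks ran from 1.33e-05 for Phgdh to 0.110 for Tstd2 in the authors' deposited table.

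The last comparison is between the 2 input libraries, which measure transcript levels. By list medians, genes of inflammation and antigen presentation were lower in the cKO, and genes of mesenchymal cells were higher, while most genes differed little. None of the genes named below for these lists had a q below 0.05 in the authors' deposited table. Of 6079 genes with a mean FPKM of at least 1, 25 were at least 2-fold higher and 26 at least 2-fold lower on the log2(FPKM + 1) scale, 99.2% lay within 2-fold, and the median difference was -0.02. The authors' deposited table calls 45 genes different, 20 higher and 25 lower, of which 3 have a q below 0.05.

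Pro-inflammatory cytokine and chemokine genes had the lowest median of all lists. All 11 of the 21 list members with a value, 9 cytokines and chemokines and the NF-kB inhibitor genes Nfkbia and Tnfaip3, were lower in the cKO, with a median of -0.58 (95% bootstrap interval -1.03 to -0.27), below all 10000 random lists (percentile 0). Cxcl1, a chemokine that attracts neutrophils, went from 45.78 FPKM in the WT to 19.98 in the cKO, Cxcl3 from 64.3 to 30.0, Il6 from 9.15 to 3.96 and Cxcl2 from 66.1 to 36.9. Of the 23 interferon-stimulated genes 12 entered the median, which was -0.35 (-0.55 to -0.16, percentile 0), with 10 of the 12 lower. The lower ones were led by Gbp3 (26.4 to 9.92 FPKM), the transcription factor gene Irf1 (47.7 to 21.4), Zbp1 (13.2 to 8.17) and Isg15 (95.0 to 68.1). Of the 16 antigen presentation genes 12 entered the median, which was -0.20 (-0.41 to -0.15, percentile 0.5), with 12 of the 12 lower. Among them were Cd74, the invariant chain of class II molecules (184 to 105 FPKM), and Tapbp (183 to 125). Of the 20 genes of Toll-like receptor and NF-kB signalling 11 entered the median, which was -0.23 (-0.40 to -0.06, percentile 0.225), with 9 of the 11 lower. Among the lower ones were Tlr2 (50.5 to 33.1 FPKM) and Nfkb2 (16.8 to 12.5). Members of every list have a value only through a listed differential peak. The part of this selection in the medians was not tested. The unfolded protein and integrated stress response list reached percentile 2.45 with a median of -0.15 (-0.29 to 0.15), although Hspa5, the main chaperone of the endoplasmic reticulum, was among its 4 higher genes (84.0 to 174.6 FPKM) and Sesn2 (15.9 to 11.1) and Trib3 (15.3 to 11.6) among its 8 lower ones.

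**Figure D3:**
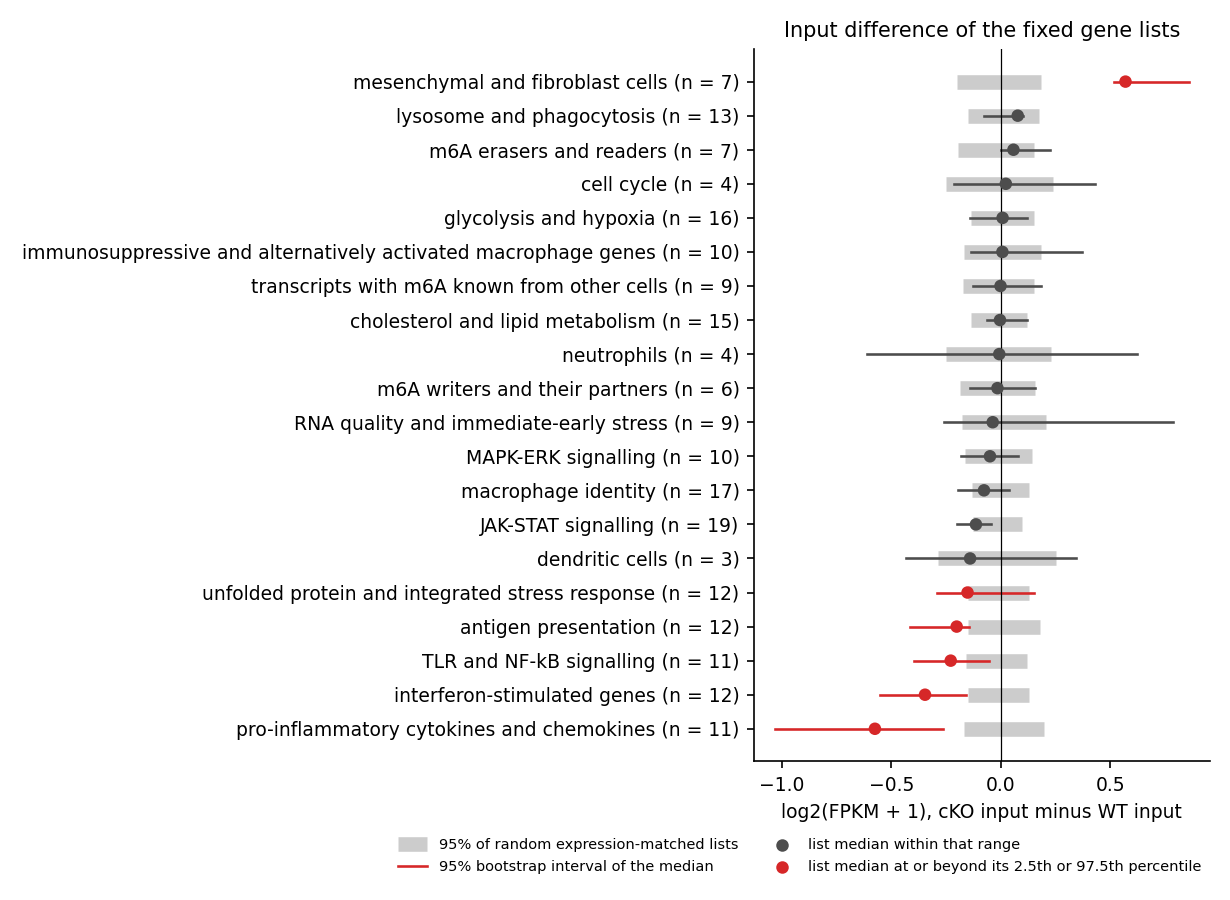
Median difference in log2(FPKM + 1), cKO input minus WT input (horizontal axis), of the gene lists with at least 3 measured genes, with the 95% bootstrap interval (line) and the range of 95% of random expression-matched lists (grey). Cytokine genes lie at -0.58 and mesenchymal genes at 0.57, the ends of the range.

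Apart from the mesenchymal list, the other lists with at least 3 measured genes stayed inside the range of random lists. Macrophage identity genes had a median of -0.08 (percentile 14.1), with Lyz2, whose promoter drives the Cre recombinase (3393 to 1980 FPKM), and Mertk (11.6 to 6.29) lower, and Fcgr1 higher (11.1 to 15.8). Only the cKO carried this Cre, so its effect on Lyz2 cannot be told apart from that of Mettl3 loss. JAK-STAT genes had a median of -0.11 (-0.20 to -0.04, percentile 4.12), with 15 of 19 lower, among them the phosphatase gene Ptpn6 (22.7 to 16.4 FPKM), while Jak1 was at 39.9 in the WT and 37.6 in the cKO. Genes of immunosuppressive and alternatively activated macrophages went both ways (median 0.01, percentile 51.4), with Spp1, which encodes osteopontin, at 244 and 702 FPKM, Arg1 at 699 and 907, and Nos2, the inducible nitric oxide synthase, at 351 and 215. The medians were -0.02 for m6A writers, 0.06 for erasers and readers, 0.08 for lysosome genes, 0.01 for glycolysis and hypoxia, -0.00 for cholesterol and lipid metabolism, 0.02 for the cell cycle, -0.05 for MAPK-ERK signalling and -0.00 for known m6A transcripts.

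Of the lists of other cell types with at least 3 measured genes, only the mesenchymal list left the range of random lists. Mesenchymal and fibroblast genes were higher in the cKO, with a median of 0.57 (0.52 to 0.86, percentile 100). Of the 14 list genes 7 entered the median, and 6 of the 7 were higher. Among them were Sparc (32.4 to 66.7 FPKM), Col1a1 (26.8 to 49.4), Col3a1 (19.14 to 34.03) and Dcn (28.7 to 43.0). Krt19, the only epithelial gene measured at an FPKM of at least 1, went from 7.05 to 10.8. Of the 16 epithelial and colon carcinoma genes, 13 had no input value, so RNA carried over from the MC38 cells was not assessed. Neutrophil genes had a median of -0.01 over 4 genes and dendritic cell genes of -0.14 over 3. Of the lymphoid genes 12 of 14 had no input value here, and of the erythroid and mast cell genes 12 of 12, so these cell types were not analysed here. In the RNA quality list (median -0.04 over 9 genes), the nuclear RNA Neat1 went from 163 to 64.1 FPKM and Malat1 from 171 to 262.1, and the near-identical Hspa1a and Hspa1b, which share reads, from 1.59 to 4.27 and from 2.62 to 5.24.

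**Figure D4:**
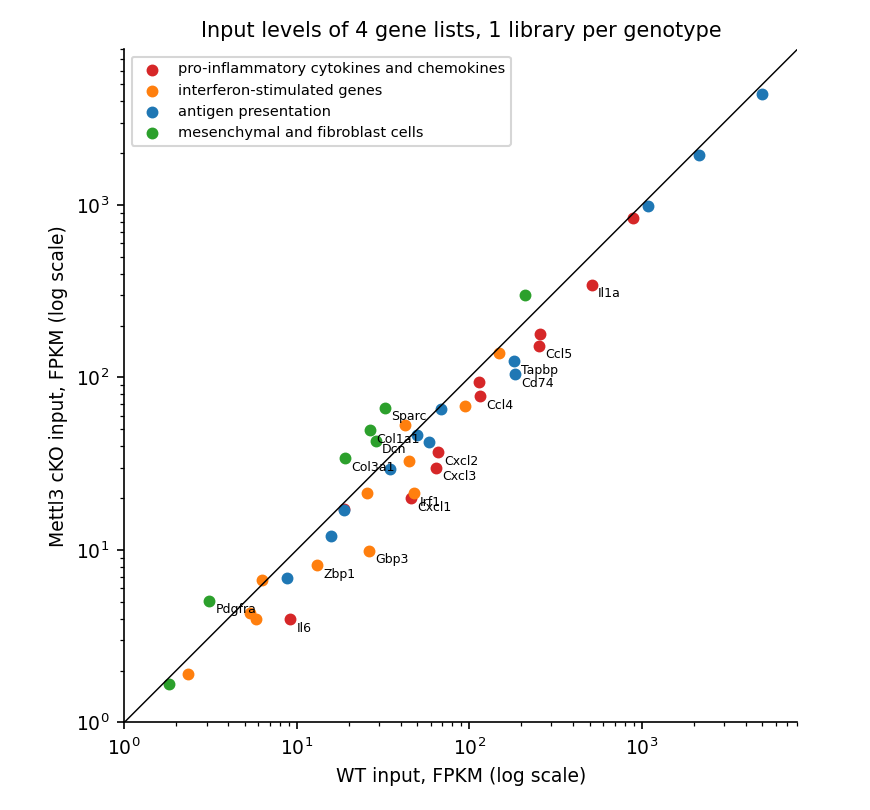
Input FPKM in the WT (horizontal axis, log scale) and the Mettl3 cKO (vertical axis, log scale) of genes of 4 lists, each point 1 gene and the line equal levels. All 11 measured members of the cytokine and chemokine list, which holds Nfkbia and Tnfaip3 as well, lie below the line and 6 of 7 mesenchymal genes above it.

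Over all genes with a mean FPKM of at least 5, Rarres2, which encodes the chemoattractant chemerin, was the lowest in the cKO (chromosome 6; 12.02 to 1.42 FPKM). It was followed by Serpina3f (19.0 to 5.10), Serpina3g (31.08 to 10.96), the complement gene C1qa (73.1 to 28.4), Neat1, Gbp3, Fcna, Slamf8, Ppp1ccb and Cxcl1. Spp1 had the largest difference among higher genes that are not ribosomal pseudogenes, followed by P4hb, a protein disulfide isomerase (249.5 to 638 FPKM), Cxcl14 (9.35 to 22.3), Hspa5, Repin1, Sparc and Clu (8.11 to 17.4). Rpl9-ps6, Rpl19-ps1 and Rpl15-ps6 are pseudogenes that share sequence with their parent genes, as does Ppp1ccb, so their values are uncertain.

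Whether transcripts with m6A in the WT differed in level was asked last. The 6016 genes with a WT peak had a median difference of -0.02 and the 63 without one of -0.08 (95% bootstrap interval -0.20 to -0.01). Against random lists of genes with a peak matched to the 63, this lay at percentile 1.02, and the matched difference was 0.07. With a WT peak of at least 4-fold enrichment as the criterion, there were 2673 genes with and 3406 without. The genes without such a peak had a median of -0.0268 (95% bootstrap interval -0.0350 to -0.0164), a matched difference of 0.0112. Matched lists drawn from the 2673 gave -0.0173 to -0.0134 in 95% of draws. That pool is smaller than the 3406, so the draws largely repeat it and their range is too narrow to judge the difference. All genes in this comparison have a listed differential peak, so the 63 were selected through one outside the WT list. Input is the denominator of the peak values, so this selection can favour genes with a lower cKO input. Whether it did so was not tested, and the difference of the 63 was not read as an effect of m6A.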

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

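The tests on cytokine genes were chosen after the result was seen, and the others before.

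At 674 peaks with an adjusted p below 0.05 in the authors' deposited table, IP lay above input in 1 genotype and below it in the other. Of these, 360 were above input in the cKO alone and 314 in the WT alone. Each rests on 1 IP and 1 input library per genotype, and the difference was not tested beyond the authors' deposited table. Their genes had a median input FPKM of 1.87 against 8.47 for the other peaks with such a p, and 12.2% were intronic against 1.14%. Among the largest changes in genes with a mean input FPKM of at least 5, opposite signs were seen with cKO minus WT differences of -7.54 in Phgdh, -6.08 in Ube2v1, -5.89 in Ei24, -5.16 in Ywhaz, -4.73 in Vdac3, -4.52 in Metap2, 5.81 in Ndrg1, 5.87 in Ube2k, 6.25 in Mbtps1 and 11.20 in Loxl2.

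Peaks that were lower in the cKO were richer in the m6A motif. Noise with regression to the mean would leave no difference at matched mean enrichment and length, yet motif-dense peaks were lower more often by 6.71 percentage points (5.11 to 8.44), which argues against it. For a smaller amount of m6A at motif sites in the cKO, a difference of at least 2 points with an interval above 0 had been set beforehand, which the 6.71 points meet, so it stays a candidate explanation. A weaker pulldown in the single cKO IP library cannot be told apart from it: the slope of cKO on WT enrichment at shared peaks was 0.907 (0.885 to 0.931), between the bound of 0.9 set for a weak pulldown and the value of 1 set against it. The slope was 0.895 with a reciprocal overlap and 0.843 in genes with a mean FPKM of at least 5, which lie on the side of a weaker pulldown.

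Cytokine and chemokine genes were lower in the cKO input. A lower share of macrophage RNA would bring macrophage identity genes down as far, but their median lay 0.50 above that of the cytokine genes (95% bootstrap interval 0.14 to 0.96). Scaling between the libraries also fails to account for it, since the median of genes with a mean FPKM of at least 5 was -0.0209 and the cytokine median stayed at -0.55 after centring on it. What stays open is that 10 of the 21 list genes had no value here, and that the other 11 entered through a listed differential peak. Of their 12 such peaks, 10 were higher in the cKO, and input is the denominator of the peak values. This selection can favour genes with a lower cKO input, and the random lists were not matched on peak direction. Its part in the difference was not tested. Also open is that 1 culture per genotype cannot separate genotype from culture, including the higher mesenchymal genes in the same library.

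Genes whose input fell tended to have higher peaks. Across genes, which are not independent replicates, Spearman's rho between the input difference and the peak difference was -0.12 at a mean FPKM of at least 5 (3537 genes, 95% bootstrap interval -0.14 to -0.08). This is the sign and size set beforehand for an effect of the input as the denominator of the peak values, although the interval reaches past the bound of -0.1. In genes with a mean FPKM of at least 50, rho was 0.0422 (549 genes, -0.04 to 0.13), as set beforehand for a relation carried by genes with few reads. A biological link between m6A and transcript level was not tested.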

How the results depend on the processing

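The changes of the differential threshold by adjusted p or by size alone, and the list medians without shared members, were chosen after seeing the data, and the other alternatives before. Of 164 alternative values, 131 stayed within the bounds set for them, 31 moved and 2 changed side, and the cause was not tested where none is named. With a fold enrichment of at least 4, 7756 WT and 7740 cKO peaks were left, 84.3% and 83.0% of which were shared; 3' UTRs held 60.3% and 61.9%, exonic sequence 12.6% and 11.3%, 5' UTRs 10.6% and 9.86%, and introns 2.69% and 3.01%. With an adjusted p below 1e-10, 13142 and 14127 peaks were left, by construction fewer. A reciprocal overlap of at least 50% gave shared shares of 48.8% and 46.1% and a median difference of 0.0259 at shared peaks, which was 0.0733 in genes with a mean FPKM of at least 5. In the authors' deposited table, an adjusted p below 0.05 with an absolute log2 of at least 1 gave 950 higher and 718 lower peaks, a higher share of 57.0%, which changes side. An adjusted p below 0.05 alone gave 2522 and 2997 (45.7%), and p below 0.05 with the size threshold 2045 and 1638 (55.5%), which also changes side. The alternative without a fold change threshold is the same as the authors' call. A pseudocount of 0.1 gave 39 genes higher and 40 lower by at least 2-fold in the input, and a mean FPKM of at least 5 gave 14 higher. Against shuffled sequence the motif excess was 6.94 percentage points in WT and 6.04 in cKO peaks, against 0.03 and -0.62 points over the windows beside the peaks. Every list median stayed within its bootstrap interval under the pseudocount, filter, centring and shared member alternatives that left at least 3 genes. The unknown depth and the single library per group limit each of these values.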

Other observations

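Gene Ontology terms, as the files assign them to genes, were ranked by the median input difference after the list results had been seen. Of 1675 terms with 10 to 200 measured genes, 168 had a median at or below the 2.5th percentile of random expression-matched lists and 44 at or above the 97.5th. Chance gives 41.9 on each side for independent terms, and terms share genes. The number of terms at the upper end was thus close to that given by chance. The lowest was defense response to protozoan (median -0.58, 95% bootstrap interval -0.82 to -0.39), with 17 of 18 genes lower. It is led by Gbp3, Il6, Gbp8, Gbp9, Gbp7 and Gbp4, and most of these are guanylate-binding proteins, which interferon-gamma induces. Genes of tRNA aminoacylation, which charge transfer RNAs with amino acids, had a median of -0.24 (-0.39 to 0.00) with 10 of 14 lower, and amino acid transporters one of -0.31 (-0.47 to 0.02) with 7 of 10 lower.

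At the other end, genes of the cytosolic large ribosomal subunit were higher in the cKO by a median of 0.31 (0.27 to 0.36), with 43 of 45 higher, and those of the small subunit by 0.29 (0.25 to 0.32), with 32 of 38. Many ribosomal protein genes share reads with pseudogenes. Protein disulfide isomerases, which fold secreted proteins in the endoplasmic reticulum, had a median of 0.31 (0.10 to 0.52) with 10 of 12 higher, led by P4hb, Pdia6, Pdia4 and Pdia3. Extracellular matrix constituents had a median of 0.30 (0.04 to 0.47) with 18 of 19 higher, led by Sparc, Col1a1, Col3a1 and Fn1.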
